A study of Anopheles gambiae with 6 samples.

How the data were processed

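RNA was taken from salivary glands dissected from last-instar Anopheles gambiae larvae (3 pools of 50 individuals) and from whole larvae (3 pools of 200), and each pool was biotin-labelled and hybridized to its own Affymetrix array. The labels describe the pools as biological repeats. Per the labels, cDNA was made from total RNA and amplified by in vitro transcription before hybridization. The deposited values are on a log2 scale, taken from their range (2.46 to 14.9) and from the name RMA, which is the only method in the submitters' processing notes. RMA usually corrects background, quantile-normalizes and summarises probes into probe sets. Its version, its settings and whether all 6 arrays were normalized together are not given in the sources used here. The 95th percentile of Anopheles values differed between the groups by 0.51 (log2), which another normalization would change. RMA gives no detection call, and the Affymetrix calls named in the series' design were not used here.

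The 22761 rows were sorted by the form of their identifiers into 16884 Anopheles probe sets, 4506 Plasmodium probe sets, 144 Affymetrix controls, 290 numeric identifiers and 937 identifiers of GenBank form. Reading the prefixes as Anopheles and Plasmodium rests on the chromosome arms named by the first (5, beside an unplaced class) and the 14 chromosome groups named by the second. Target and organism of the numeric and GenBank-style identifiers are not given in the sources used here. A gene table of assembly idAnoGambNW_F1_1 with 15165 genes matched 0 probe sets, and the files do not pair identifiers with genes. The 27 gene lists fixed in advance were therefore not tested (0 of 27), nor were the set tests, the rule for named genes by description or centring on ribosomal proteins.

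Differences between gland and whole larva were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), over the Anopheles probe sets of all 6 arrays with the group as the only term and Benjamini-Hochberg adjustment. A probe set was counted at adjusted p under 0.01 with at least a 2-fold difference, and with the brighter group above a floor on all 3 of its arrays. The floor was the 95th percentile of 4502 Plasmodium probe sets that name a chromosome group, taken on each array. It removed no call: 403 and 843 probe sets passed without it too. The series' design used a 2-fold difference, detection on all gland arrays and a false discovery rate of 1% with a plain test, and limma took the place of that test. Actin, Gapdh and the other controls were read from 1 limma fit over all rows. Since genes could not be named, the identifiers with the largest difference in each direction, among those past the count rule with non-overlapping groups, were printed, 2 each way.

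Chromosome arms were compared by Fisher's exact test and by 10000 rotations of the calls along identifier order, and shares carry exact binomial 95% intervals. Neighbouring identifiers were compared with 1000 shuffles within arms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No pair of arrays held identical values (0 pairs). Array dates or batches were not given in the sources used here.

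The fit was tested on simulated data for gland against whole larva, with 16884 probe sets given the levels and SDs of the real groups. Of 50 probe sets changed at each size, an adjusted p under 0.01 alone recovered 1 at 1.5-fold, 17 at 2-fold, 30 at 4-fold and 45 at 8-fold, and called 7 unchanged ones. With the 2-fold limit, which by itself removes most 1.5-fold changes and part of the 2-fold ones, 0, 11, 30 and 45 were recovered and 6 unchanged ones were called. With and without that limit, unchanged probe sets made up a larger share of the calls than the nominal 1%. This was a single simulated data set with fewer changed probe sets than the 1246 calls in the real data. The median standard error of a difference was 0.191 (log2).

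Alternatives set before the data were examined were the series' plain test, eBayes without trend and with robust variances, a replicate block, centring on the Anopheles median, repeated quantile normalization, other floors, leaving out dim or cross-hybridising probe sets, 1 probe set per identifier number in place of per gene, other thresholds, array weights and leaving out each array. Probe sets are called cross-hybridising here by the identifier suffixes _s_at and _x_at alone. The numeric-identifier floor and centring on the numeric-identifier median were added after the data were seen, as were folds taken with values raised to the numeric floor on each array. So were the comparisons of chromosome arms, neighbouring identifiers, and actin and Gapdh control probe sets, with their alternatives.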

Results

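Transcript levels were measured in last-instar larvae of the malaria mosquito Anopheles gambiae, strain G3, on 6 Affymetrix arrays. Of these, 3 arrays carried RNA from dissected salivary glands, each pooled from 50 larvae, and 3 carried RNA from whole larvae, each pooled from 200. The comparison asked which transcripts were detected in the larval gland and which were more abundant there than in the whole animal. The deposited table held log2 RMA values for 22761 probe sets. Of these, 16884 had identifiers of Anopheles form, which name a chromosome arm, and these were tested. The files do not pair the Anopheles identifiers with gene names, so transcripts are described below by identifier, by chromosome arm and, for actin and Gapdh, by the array's named control probe sets. For arrays, the number of arrays limits the precision.

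Arrays of one tissue resembled each other more than arrays of different tissues. Across the Anopheles probe sets, which are not independent replicates, Pearson's r was 0.971 to 0.986 between gland arrays, 0.926 to 0.941 between whole-larva arrays and 0.795 to 0.836 between the groups. The median Anopheles value was 5.84 ± 0.014 in gland and 5.87 ± 0.043 in whole larvae (SD, n = 3 each). The 95th percentile was 9.05 ± 0.036 in gland and 9.56 ± 0.10 in whole larvae (SD, n = 3 each). Replicates varied more among whole-larva arrays. The median SD per Anopheles probe set was 0.262 in whole larvae and 0.146 in gland, a ratio of 1.80, and the whole-larva SD was the larger one for 74.6% of probe sets. The hybridization spikes, which come from no mosquito RNA, also varied more on whole-larva arrays. Their SDs there were 0.53 (bioB), 0.68 (bioC), 0.68 (bioD) and 0.43 (cre), against 0.11, 0.20, 0.12 and 0.12 in gland (n = 3 each). The larger spread was therefore not confined to mosquito RNA.

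Nearly all Anopheles probe sets were brighter than most probe sets of Plasmodium form, which served as the detection floor. On all 3 gland arrays 15501 probe sets (91.8%) exceeded the floor, and on all 3 whole-larva arrays 15570 (92.2%) did. Both groups shared 15208 of these, 293 passed in gland alone and 362 in whole larvae alone. This floor was low, at 4.14 ± 0.032 in gland and 3.96 ± 0.10 in whole larvae (SD, n = 3 each), so the counts give brightness above Plasmodium probe sets rather than a list of expressed genes. With a higher floor, chosen after the data were seen and set by 290 probe sets with purely numeric identifiers, 4014 Anopheles probe sets passed in gland (23.8%) and 6244 in whole larvae (37.0%), of which 3741 passed in both, 273 in gland alone and 2503 in whole larvae alone. The numeric floor itself lay at 6.65 ± 0.036 in gland and 6.02 ± 0.075 in whole larvae (SD, n = 3 each), and the median of these 290 probe sets was 0.42 higher in gland on the log2 scale.

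In the gland, 403 Anopheles probe sets were higher than in whole larvae (2.39% of 16884) and 843 were lower (4.99%). These passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.01 with a difference of at least 2-fold, and the brighter group lay above the floor on all 3 arrays. The higher probe sets had a median log2 difference of 1.80 (interquartile range 1.33 to 2.42), or 3.48-fold. The lower ones had a median of -2.44 (interquartile range -3.60 to -1.75), or 5.44-fold lower in gland. Large differences were mostly deficits in the gland: 165 probe sets were at least 4-fold higher and 544 at least 4-fold lower, 25 and 160 passed 16-fold, and 1 and 76 passed 32-fold. Whole larvae also hold the gland, so a part was compared with the whole, and rises and deficits are not symmetric by design. Measured folds of dim probe sets depend on the background. With values under the numeric floor raised to it, a bound added after the data were seen, 326 higher and 612 lower kept a 2-fold difference, 149 and 344 passed 4-fold, 23 and 90 passed 16-fold, and 1 and 31 passed 32-fold. Higher calls stood less clear of the numeric-identifier probe sets than lower calls, in a comparison chosen after the data were seen. At the same unadjusted limma limit (0.000813) and 2-fold, 6 of those 290 were higher (2.07%) and 0 lower, against 2.55% and 5.19% of Anopheles probe sets and 0.898% and 1.60% of the 4119 Anopheles probe sets of matched level. Of 4506 Plasmodium probe sets, which are dimmer, 3 were higher (0.067%) and 0 lower at that limit. Fisher's exact test on the higher share gave p = 0.849 against all Anopheles probe sets and p = 0.0601 against the matched ones. At 4-fold, 0 of the 290 and 167 Anopheles probe sets were higher (Fisher's exact p = 0.122). The 290 shifted toward gland as a class (median difference 0.37, 91.4% above 0) and were dim, with a median level of 4.78. The 403 higher calls had a median gland level of 8.81. Of the 430 Anopheles probe sets higher at the unadjusted limit and 2-fold, 37 were among the matched ones. The share of the 290 is therefore not a rate of false calls for the 403.

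**Figure D1:**
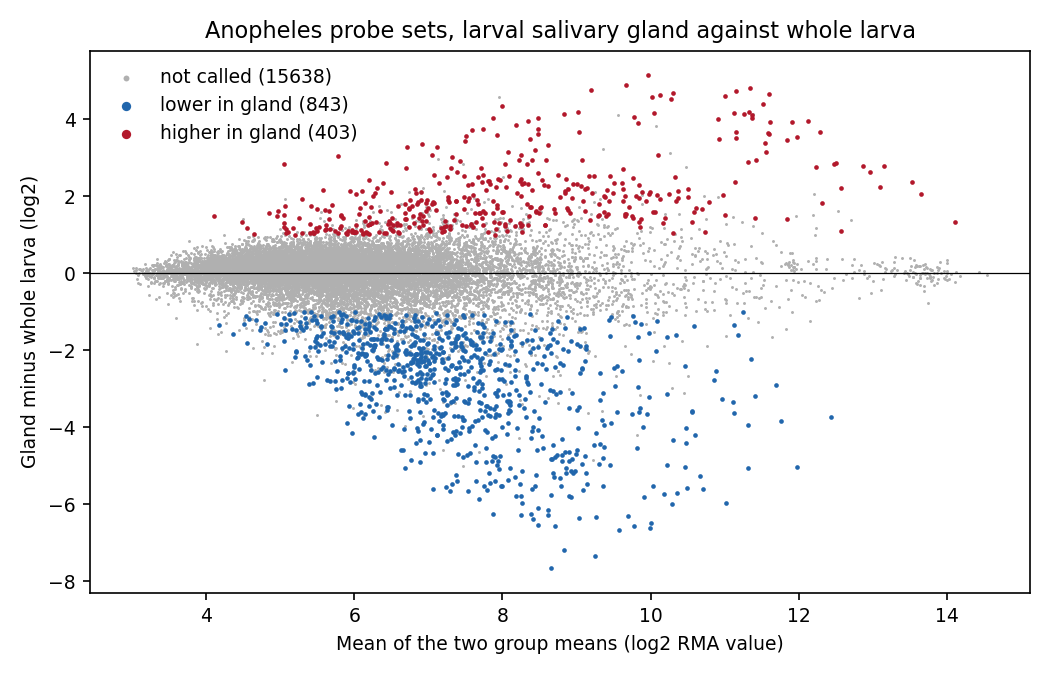
Each point is an Anopheles probe set, with the mean of the group means on the horizontal axis (log2 RMA value) and gland minus whole larva on the vertical axis (log2). Red points mark the 403 probe sets higher in gland, blue points the 843 lower and grey points the remainder; differences below 0 reach -7.66 and those above 0 reach 5.14.

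Most of the higher transcripts exceeded the numeric floor on at least 1 whole-larva array too, whereas most of the lower ones did not exceed it on any gland array. The median level of the 403 higher probe sets was 8.81 in gland and 6.76 in whole larvae, and that of the 843 lower ones was 5.83 in gland and 8.54 in whole larvae. Of the higher probe sets, 97 lay at or below the numeric floor on all 3 whole-larva arrays. Of the lower ones, 580 lay at or below it on all 3 gland arrays. The numeric floor itself was 0.63 higher on gland arrays (log2), which adds to this contrast. Most Anopheles probe sets, called or not, also lay under it in gland. Of 16884, between 4568 and 4738 exceeded it on a single gland array, and between 7044 and 8032 on a single whole-larva array. Lying under this floor in gland was therefore not particular to the lower calls. Every one of the 403 and 843 had groups that did not overlap. Selection by a small p and a 2-fold difference favours this, so it is not separate support for the calls. Over all Anopheles probe sets, the 3 gland values lay above the 3 whole-larva values for 4048 (24.0%) and below them for 2992 (17.7%), where chance gives 5% in each direction, 10% in both together.

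The largest rise was in Ag.X.814.0_CDS_at, on the X chromosome, with 12.53 ± 0.43 in gland and 7.39 ± 0.48 in whole larvae (SD, n = 3 each). Its log2 difference was 5.14 (SE 0.328, limma adjusted p = 7.48e-05), or 35.4-fold. Ag.2R.1578.0_CDS_at, on arm 2R, followed with 12.11 ± 0.14 in gland and 7.22 ± 0.27 in whole larvae (SD, n = 3 each), a log2 difference of 4.88 (SE 0.227, limma adjusted p = 2.56e-05), or 29.5-fold. The order of these rises reversed without gland replicate 3 (4.90 on X, 4.91 on 2R) and without whole-larva replicate 3 (4.89 and 4.92). It held in the other fits with 1 array left out. The largest measured deficits were in Ag.2R.3186.0_CDS_at and Ag.3R.837.0_CDS_at, whose gland values lay under the numeric floor on all 3 arrays, so that their folds are given as bounds against that floor. Ag.2R.3186.0_CDS_at measured 4.83 ± 0.12 in gland and 12.49 ± 0.50 in whole larvae (SD, n = 3 each). The measured log2 difference was -7.66 (SE 0.284, limma adjusted p = 2.11e-05), and whole larvae were at least 57.3-fold brighter. Ag.3R.837.0_CDS_at measured 5.59 ± 0.30 in gland and 12.92 ± 0.14 in whole larvae (SD, n = 3 each), a log2 difference of -7.34 (SE 0.233, limma adjusted p = 2.11e-05), and whole larvae were at least 77.3-fold brighter. The order of these deficits by measured difference was the opposite of that by bound.

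Both the counts and their balance depended on the setting. Leaving out gland replicate 1, 2 or 3 left 194, 146 or 188 higher and 472, 410 or 452 lower. Without whole-larva replicate 1, 2 or 3 there were 407, 327 or 349 higher and 1044, 742 or 1011 lower. The equal-variance test named in the series' design, after Benjamini-Hochberg adjustment, left 34 higher and 97 lower. The share of calls that were lower, 67.7%, became 55.8% (658 higher, 830 lower) after quantile normalization was applied again and 88.4% (207 higher, 1576 lower) after each array was centred on the numeric-identifier probe sets, a scaling chosen after the data were seen that moved the median difference of all Anopheles probe sets from 0.068 to -0.36.

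Gapdh, a glycolytic enzyme, was lower in gland at all 3 of its control probe sets, and actin, a cytoskeletal protein, differed less. The middle Gapdh probe set measured 11.01 ± 0.092 in gland and 12.83 ± 0.52 in whole larvae (SD, n = 3 each), a log2 difference of -1.82 (SE 0.285, limma adjusted p = 0.00124 over the 6 actin and Gapdh probe sets). The 3′ probe set differed by -1.34 (SE 0.280) and the 5′ probe set by -1.23 (SE 0.271), each with a limma adjusted p of 0.00368. In folds, whole larvae were 3.54, 2.53 and 2.35 times as bright at the middle, 3′ and 5′ probe sets. Every whole-larva array was brighter than every gland array at each of them. Actin differed by -0.75 at its 3′ probe set (SE 0.245, limma adjusted p = 0.0237), by -0.32 at its 5′ probe set (SE 0.235, adjusted p = 0.260) and by -0.17 in the middle (SE 0.248, adjusted p = 0.512), and none of these passed 0.01. Adjusted over all 22761 probe sets, the limma p was 0.00465 for the middle Gapdh probe set, 0.0172 for 3′ and 0.0205 for 5′. Over the 6 probe sets, the middle one missed 0.01 without gland replicate 2 (0.0102), the 3′ one without gland replicate 1 (0.0153) or 2 (0.0249), and the 5′ one without gland replicate 1 (0.0153), 2 (0.0249) or 3 (0.0109). Actin at 3′ passed 0.01 without whole-larva replicate 3 (0.00656) and after centring on the numeric-identifier probe sets (0.00351).

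The 3′ minus 5′ difference of the control probe sets, a common measure of RNA quality, was compared between the tissues. That of actin was 1.03 ± 0.12 in gland and 1.47 ± 0.16 in whole larvae (log2; SD, n = 3 each), with no overlap and an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. That of Gapdh was 0.777 ± 0.14 in gland and 0.881 ± 0.058 in whole larvae (SD, n = 3 each; exact two-sided permutation p = 0.3).

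**Figure D2:**
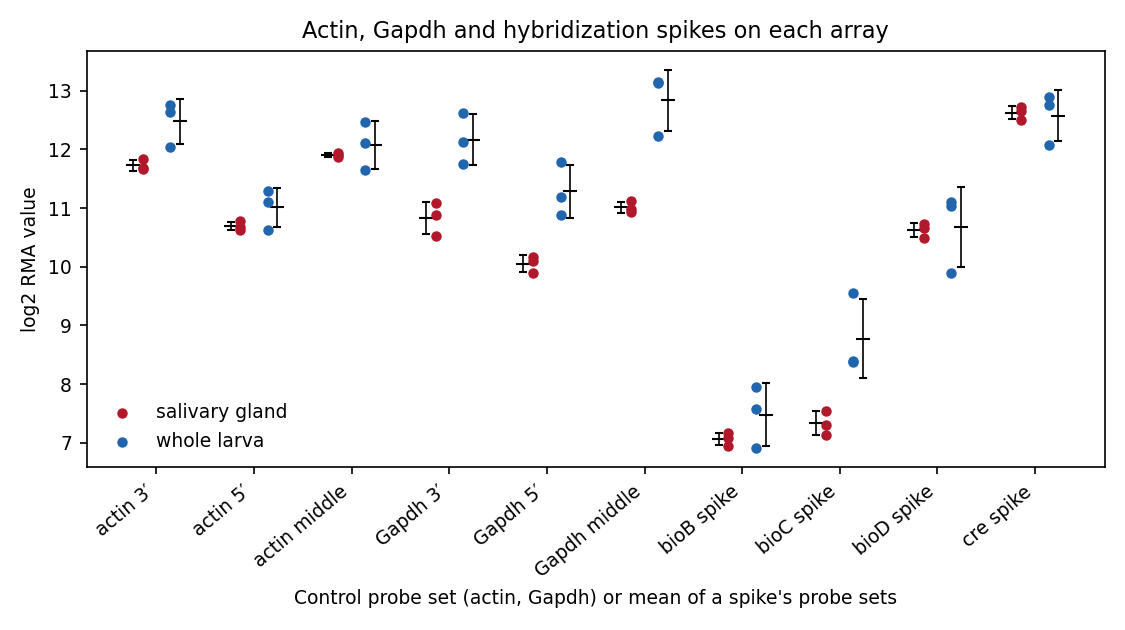
The vertical axis gives log2 RMA values of the actin and Gapdh control probe sets and the mean of each hybridization spike's probe sets, with a point per array (red gland, blue whole larva) and the group mean ± SD beside it. Gapdh lies lower on the gland arrays at all 3 probe sets, and the bioC spike averages 7.33 on gland and 8.77 on whole-larva arrays.

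Calls were spread over all chromosome arms in both directions. Probe sets higher in gland made up 2.77% of arm 2L, 2.03% of 2R, 2.81% of 3L, 2.83% of 3R and 2.57% of X. Probe sets lower in gland made up 5.37% of 2L, 6.42% of 2R, 5.85% of 3L, 4.75% of 3R and 3.14% of X. Among 1938 probe sets that name no placed arm, 1.14% were higher and 1.70% lower. Compared with the other placed arms by Fisher's exact test (adjusted over 12 tests), lower calls were fewer on X (odds ratio 0.540, adjusted p = 1.43e-04) and more frequent on 2R (odds ratio 1.30, adjusted p = 0.00173), and higher calls were fewer on 2R (odds ratio 0.726, adjusted p = 0.0214). Unplaced probe sets had fewer calls than placed ones, with odds ratios of 0.439 for higher (adjusted p = 1.43e-04) and 0.302 for lower (adjusted p = 2.82e-14). Fisher's test treats probe sets as independent. The calls were therefore also rotated 10000 times along the identifier order, which keeps neighbouring calls together. In this permutation test no difference between placed arms passed 0.05 (smallest adjusted permutation p = 0.857). Rotated positions overlap, so the permutation test does not decide whether the differences between arms hold. The deficit of higher calls on 2R also missed 0.05 with the numeric floor (adjusted p = 0.0523), and at 4-fold 3L had more higher calls (odds ratio 1.65, adjusted p = 0.0175) and 3R had fewer lower ones (odds ratio 0.738, adjusted p = 0.0175), both settings chosen after the data were seen.

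**Figure D3:**
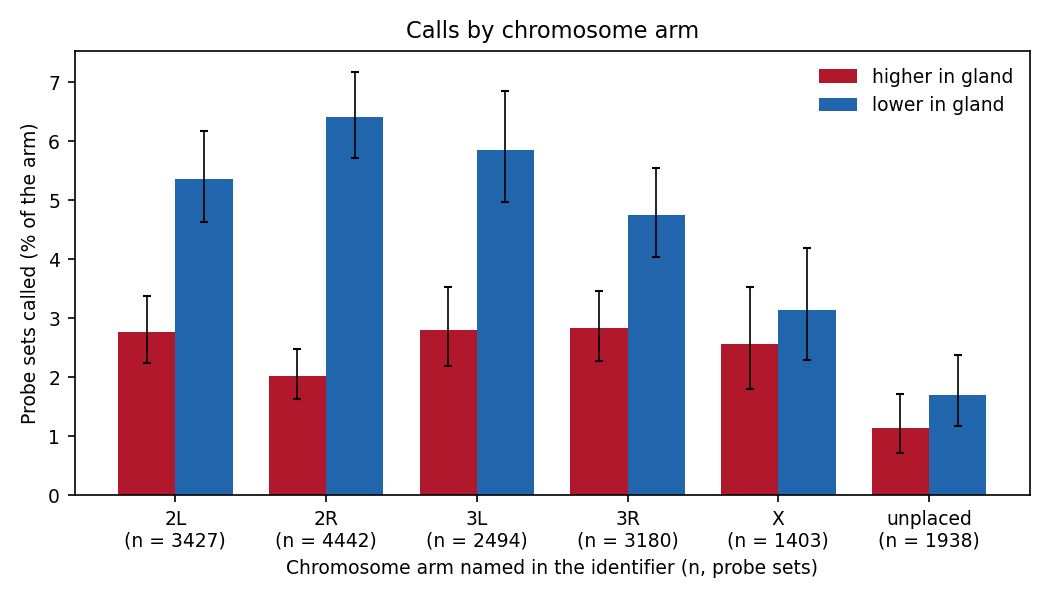
Bars show the percentage of Anopheles probe sets on each chromosome arm that were higher (red) or lower (blue) in gland, with exact binomial 95% intervals, and n is the number of probe sets. Lower calls exceed higher calls on every arm, from 3.14% of X to 6.42% of 2R among placed arms.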

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

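The tests of the bioC spike, the numeric identifiers and the neighbouring identifiers were chosen after the result was seen, and so was the wording of the prediction for the other splits; the search for probe sequences was set beforehand.

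Other splits of the 6 arrays into 3 and 3 gave 0 calls at most in one direction, against 403 higher and 843 lower for gland against whole larva, so 1 of the 10 splits reached the real count in each direction. With 10 splits a share under 0.1 cannot be had. Every other split put arrays of both tissues on each side, so the tissue difference entered its residual variance and left little room for calls. The other splits therefore do not show how many calls chance alone would give.

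The bioC hybridization spike, which comes from no mosquito RNA, was brighter on the whole-larva arrays, at 8.77 ± 0.68 against 7.33 ± 0.20 in gland (SD, n = 3 each), a gap of 1.45 (SE 0.409). It drew attention as a group difference in controls outside the main measurement. A different amount of the whole spike mix would move the other spikes alike, but the whole minus gland difference of bioC exceeded the mean difference of bioB, bioD and cre by 1.31 (SE 0.344), which argues against it. Level-dependent normalization is argued against by the 2903 Anopheles probe sets at levels 7 to 9, whose median whole minus gland difference was 0.077. Arrays handled in separate batches cannot be told apart from the groups, since bioC on the dimmest whole-larva array lay 0.829 above the brightest gland array and no batch is given in the sources used here; no biological explanation was tested.

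Probe sets with numeric identifiers shifted toward gland, with 91.4% above 0, a median difference of 0.37, and 6 higher and 0 lower among 290 (limma, adjusted over the class; 155 and 1 at an unadjusted p under 0.05). They drew attention because a signal moved with the groups in probe sets whose target is not given in the sources used here. One offset per array that moves dim and bright probe sets alike is argued against by the shift of numeric minus Plasmodium probe sets, 0.331 (95% bootstrap interval 0.271 to 0.372). The Plasmodium probe sets are dimmer, with a median level of 3.19 against 4.78, so they do not address an offset that is compressed at low levels. Level-dependent normalization is argued against by the shift of numeric minus level-matched Anopheles probe sets, 0.295 (0.241 to 0.334). These intervals resample probe sets, not arrays, so they carry no variation between arrays. Binding that depends on probe sequence stays open, since 0 probe sequences were in the files used here, and so does a biological difference between the tissues, as untested. The level-matched Anopheles probe sets themselves moved by a median of 0.078.

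Called probe sets lay next to each other in identifier number more often than by shuffling: 69 pairs of consecutive numbers were both lower, against 36.7 by chance (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give), and 16 pairs were both higher, against 9.02 (p = 0.023). Several probe sets per number do not account for it, since each number counted once in those 69 pairs. Nor do probe sets with the suffixes _s_at and _x_at, since without them 58 lower pairs stood against 30.4. Cross-hybridisation of other probe sets was not tested, since probe sequences were not in the files used here. The excess of lower pairs fell with distance, from 1.88 times chance at 1 to 1.10 at 50 (permutation p = 0.281), whereas that of higher pairs did not fall step by step, with 1.77 at 1, 0.992 at 2, 0.780 at 3, 1.11 at 5, 1.22 at 10 and 1.33 at 50. For lower calls the fall could reflect genes of like expression lying side by side, as a hypothesis, if numbers follow position, which the sources used here do not state. For higher calls the 16 pairs leave this open, and whether neighbouring numbers cover 1 gene was not tested.

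Among 937 probe sets with identifiers of GenBank form, whose organism is not given in the sources used here, 12 were higher and 3 lower in gland (limma, adjusted over the class), a signal outside the Anopheles comparison.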

How the results depend on the processing

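The numeric-identifier floor, the centring and folds on it, and the arm, actin and Gapdh alternatives were chosen after the data were seen. Against 403 higher and 843 lower, counts stayed within 1.5 times under the series' test at p under 0.01, eBayes without trend or robust, centring on the Anopheles median, leaving out dim or cross-hybridising probe sets, 1 probe set per number, other floors, folds taken at the numeric floor and array weights. They moved further after the series' test with Benjamini-Hochberg adjustment (34 higher, 97 lower), at 4-fold (165, 544), at adjusted p under 0.05 (611, 1301), after repeated quantile normalization (658 higher) and after centring on the numeric-identifier median (207, 1576). Leaving out 1 array gave 146 to 407 higher and 410 to 1044 lower, of which 146 to 333 and 410 to 766 were among the main calls. Without gland replicate 1, 2 or 3 the counts were 194, 146 and 188 higher and 472, 410 and 452 lower. Without whole-larva replicate 1, 2 or 3 they were 407, 327 and 349 higher and 1044, 742 and 1011 lower. Each of these fits had 1 array fewer, so the number of arrays alone does not account for the fall without a gland array. Every fit took 1 variance per probe set over both groups, whose median SDs were 0.146 in gland and 0.262 in whole larvae. Without a gland array, more of that variance came from whole larvae. The stricter thresholds lower counts by construction; the cause was not tested for the others. With the replicate block, 253 were higher and 698 lower. Same-numbered arrays deviated from their group means with r of 0.102, -0.087 and -0.002, and not every array correlated best with its own number. The values thus gave no sign that the numbers pair the arrays, but 3 arrays per group cannot decide it. Detection in gland fell to 9640 with the 99th percentile floor and to 4014 with the numeric floor, and in whole larvae to 6244 with the numeric floor. Without a floor every probe set counts as detected. For the 4 named probe sets, 39 comparisons kept their side of the threshold and 1 did not (Ag.X.814.0_CDS_at had 0.011 after the series' test, within 6.23e-05 to 0.011). Of the arm tests, 40 kept their side of 0.05, 2 gained it and 4 lost it. All 3 differences between placed arms that passed Fisher's test missed 0.05 when calls were rotated along identifier order (adjusted rotation p = 0.857 each). Rotated positions overlap, so this does not decide whether the differences hold. Higher calls on 2R also missed 0.05 with the numeric floor. Of the actin and Gapdh tests, 46 kept their side of 0.01, 2 gained it and 6 lost it. No call among these named probe sets, arms and controls reversed; reversals among all 403 and 843 calls were not counted. Centring on ribosomal proteins, gene list tests and 1 probe set per gene were not run, since no gene names were matched. Signal over background limits the dim probe sets, since 23.8% of probe sets passed the numeric floor on all gland arrays.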

Other observations

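The tests of identifiers that name a UTR and of shared identifier numbers were chosen after the result was seen. Probe sets whose identifier names a UTR were called lower in gland more often than those that name a CDS, 9.49% of 790 against 4.82% of 14060 (odds ratio 2.07, 95% interval 1.59 to 2.66, Fisher's exact p = 1.60e-07). They were also brighter, with a median level of 7.06 against 5.84. Compared within 6 bins of mean level by an exact Mantel-Haenszel test, the odds ratio for lower calls was 1.17 (0.890 to 1.53, p = 0.236). For higher calls it was 0.383 (0.223 to 0.624, exact p = 2.23e-05) within bins and 1.03 (0.608 to 1.64) without them. Probe sets of 1 number are not independent, so these p-values are too small.

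Some called probe sets share their identifier number with other probe sets, here called partners. Of 98 higher calls with a partner, 47 had a partner called higher, where random partners gave a mean of 2.81, and 88 had only partners of the same sign, called or not, where random partners gave 52.0. Of 270 lower calls, 174 had a partner called lower (random 22.3) and 242 had only partners of the same sign (random 86.3). Each random mean comes from 1000 draws of as many Anopheles probe sets. Opposite calls within 1 number involved 1 higher and 2 lower probe sets.

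Runs of neighbouring numbers were short. No run of 3 or more consecutive numbers was higher in gland (0 runs), 4 were lower, and the longest held 4 numbers on arm 3L.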
